A study of Rattus norvegicus with 48 samples.

How the data were processed

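Lung tissue from 48 male Sprague-Dawley rats weighing about 200 to 250 g at the outset was profiled by RNA sequencing, 1 library per animal. Per the labels' protocols, total RNA was extracted from a piece of lung with a miRNeasy kit, and 1 µg per animal went into a stranded TruSeq total RNA library after depletion of ribosomal RNA, with 12 cycles of PCR. Such libraries hold coding and long noncoding RNA, and carry no molecular identifiers. Per the submitters' processing notes, bcl2fastq 2.19, Trimmomatic 0.35, HISAT2 2.1.0, SAMtools 1.8 and HTSeq 0.6.1 were used with the rat build Rnor_6.0. The gene annotation and the strand setting of the counting were not given in the sources used here, so values of antisense and overlapping genes are uncertain. The same holds for near-identical copies whose reads can be split, such as the globin genes Hbb and Hba1 and the Cyp2b genes around Cyp2b1.

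The authors deposited raw read counts per gene symbol in 2 tables, 1 per exposure schedule, each with 24 columns of whole numbers. Both tables held the same 30045 genes, of which 5463 were at 0 in all libraries, and 0 columns belonged to no sample. Columns were matched to animals by the animal number, schedule, time and treatment in their names. Of the gene symbols, 19082 matched a current symbol of the RefSeq table for the assembly GRCr8 and 2412 matched only an older synonym. Because that assembly differs from the build of the counts, no coordinates were taken from it. For animal 32 the description named the table of the other schedule, whereas its title and column placed it in the single-exposure table, which was followed.

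Library totals ranged from 1.54 to 7.16 M (mega) counts, with a mean of 5.18 ± 1.02 M (SD, n = 48). A count of 3, taken as the floor that a count of 0 allows, corresponded to 0.419 to 1.95 CPM, counts scaled to the library total. Floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The SDs and standard errors given below include the spread between animals. All 120 pairs of libraries within a group differed by more than sampling noise, with a chi-square per gene between 2.70 and 108, so each library counted as 1 animal.

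Groups were taken from the labels, 8 groups of 6 animals. Each comparison within a schedule used the 24 libraries of that schedule in a single group-means model in edgeR 4.0.16 (R 4.3.3). Counts were normalized by TMM, low genes were removed with filterByExpr, and contrasts were tested two-sided with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. Differences between oil vapor effects at both times were tested as interactions in the same fit. Differences between schedules were tested as interactions in a fit of all 48 libraries, in which any shift between the tables cancels. Fold changes are given as log2 values with their standard errors, and levels as CPM with the SD over 6 animals. Each standard error (SE) was derived as the absolute log2 value divided by the square root of the F of the quasi-likelihood test. It is approximate, most of all for genes near 0 in a group.

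Gene lists, 48 in all, covered response pathways, lung, airway and blood cell types, and signs of RNA quality. Lists with at least 5 measured members were tested with limma 3.58.1, which left 45 lists per comparison. Tests were camera with a preset correlation of 0.01, camera with the correlation estimated from the data, and fry, each adjusted over the lists of a comparison. Camera compares a list with other genes, while fry tests whether its members move on balance in 1 direction, and fry's mixed test whether they change in either direction. A list of mitochondrially encoded transcripts was not analysed here. Members were also adjusted over the list alone.

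Groups, designs, gene lists and the other settings tried were set before the data were examined. So was the rule for named genes. For each oil vapor contrast it took the 10 genes with a symbol and the smallest p in each direction among those past the threshold with a mean of at least 1 CPM. Where fewer than 10 passed, it added the 5 genes with a symbol and the smallest p, given as values that did not pass. It also took 2 to 4 members with the smallest p of each list described, and 5 genes for each interaction and each contrast of air groups. Some members that the rule would name are not reported here. LOC306766 and Lbp among the schedule differences, and genes named only under an alternative setting, fell outside that rule and were chosen after their values were seen.

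Settings tried in place of the main ones were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with sample weights, only the 12 libraries compared, all 48 libraries, 1 surrogate variable from sva 3.50.0, a minimum of 1.5-fold, and leaving out each animal of an oil vapor contrast in turn. After the data were seen, scores of liver, heart, and spleen and bone marrow transcripts were added as covariates, and animals 5 and 43 were left out of further comparisons. List tests on the contrasts of air groups and the pairing of libraries across schedules were also added then. The spleen and bone marrow score was mostly counts of Alas2, an erythroid gene of the lists tested. At 28 days the heart and marrow scores also had lower ranges in oil vapor than in air. A blood or heart list that turns with these scores is therefore no independent check. Every count was set against 100 splits of the same animals.

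The test was checked on simulated counts drawn from the means and library sizes of these animals, with 100 genes changed 1.5-fold and 100 changed 2-fold. For the single exposure at 1 day, with 14729 genes, it recovered 64% of genes changed 1.5-fold and 86% of those changed 2-fold, with 9 false calls among 159. For the repeated exposure at 1 day, with 14929 genes, it recovered 51% and 84%, with 11 false calls among 146. These rates describe the simulated counts only. Recovery was not checked in real libraries, some of which were rich in transcripts of other tissues. A split of the real animals other than the true grouping called 222 genes for the difference between schedules. The simulated rates therefore need not hold for these animals. The pairing test found the shared quantity in 100% of 200 simulations, and gave a p below 0.05 in 4.5% of simulations without one.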

Results

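The response of the rat lung to inhaled oil vapor was examined by RNA sequencing after a single 6 h exposure at 300 ppm or after the same daily exposure on 4 days per week for 4 weeks. The longer schedule comprised 16 exposure days. Rats breathed filtered air or oil vapor in whole-body chambers, and lungs were taken 1 or 28 days after the last exposure, with 6 animals in each of the 8 groups. After the single exposure, library totals were 4.96 ± 0.401 M counts (mega, SD, n = 6) in air and 5.44 ± 1.34 M in oil vapor at 1 day, and 4.62 ± 0.944 and 5.29 ± 0.615 M at 28 days. After the repeated exposure they were 5.38 ± 0.634 and 5.14 ± 2.11 M at 1 day, and 5.13 ± 0.775 and 5.47 ± 0.602 M at 28 days. Animal 43, from the repeated oil vapor group at 1 day, had the shallowest library, with 1.54 M counts and 16830 genes detected, and 12.2% of its counts fell in its 10 most abundant genes.

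Transcripts of blood-forming tissue varied widely within groups, and at like counts in both schedules, as did those of liver in part of the groups. Alas2, the erythroid enzyme that starts heme synthesis, had 27026 counts in animal 5 (single exposure, oil vapor, 1 day) and 30019 counts in animal 43. Those libraries differed in depth, 4.74 against 1.54 M, and in Sftpc, the surfactant protein of alveolar type 2 cells, 24969 against 3203 counts. Alb, the liver-made serum albumin, reached 3592 counts in animal 17 and 3873 in animal 82, the animals of the lowest number in the air groups at 28 days. After this was seen, animals were ranked by number within each group and set beside the animal of the same rank in the matching group of the other schedule, which gave 24 pairs of unrelated animals. Over these pairs, counts of 9 spleen and bone marrow transcripts, log2-transformed and centred within groups, correlated with Pearson r = 0.988 and Spearman rho = 0.957. Each had a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Over a family of 13 tests the adjusted p was 4.3e-05 for r and 6.5e-05 for rho, and r was 0.984 without the 2 pairs farthest from the median. Within the 4 group pairs, r was 0.998 (exact permutation p = 0.00278), 0.991 (exact p = 0.00139), 0.999 (exact p = 0.00139) and 0.967 (exact p = 0.00694). Alas2, among the counts that prompted the pairing, made up most of the summed marrow counts, with a mean of 5013 of 5551 per library. Of 6 marrow genes compared singly, 2 had a pair r over 0.8. So did 10 of 11 erythroid genes, whose sum gave r = 0.942 (permutation p = 1e-05). Liver transcripts gave r = 0.941 (permutation p = 3e-05, adjusted p = 9.8e-05) and rho = 0.495 (permutation p = 0.0123, adjusted p = 0.0401), with r = 0.871 without the 2 farthest pairs. Within the group pairs, liver r was 0.706 (exact permutation p = 0.117) and 0.936 (exact p = 0.00139) for air and oil vapor at 1 day, and 0.981 (exact p = 0.0222) and -0.132 (exact p = 0.567) at 28 days. Brain transcripts gave r = 0.92 (permutation p = 1e-05, adjusted p = 4.3e-05) and rho = 0.857 (permutation p = 1e-05, adjusted p = 6.5e-05), with r = 0.866 without the 2 farthest pairs and 1 of 8 genes over 0.8. Alveolar type 2 transcripts gave r = 0.35 (permutation p = 0.166, adjusted p = 0.166) and rho = 0.014 (permutation p = 0.488, adjusted p = 0.488), with r = 0.306 without the 2 farthest pairs. The plot of 4 marker transcripts shows these pairs.

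**Figure D1:**
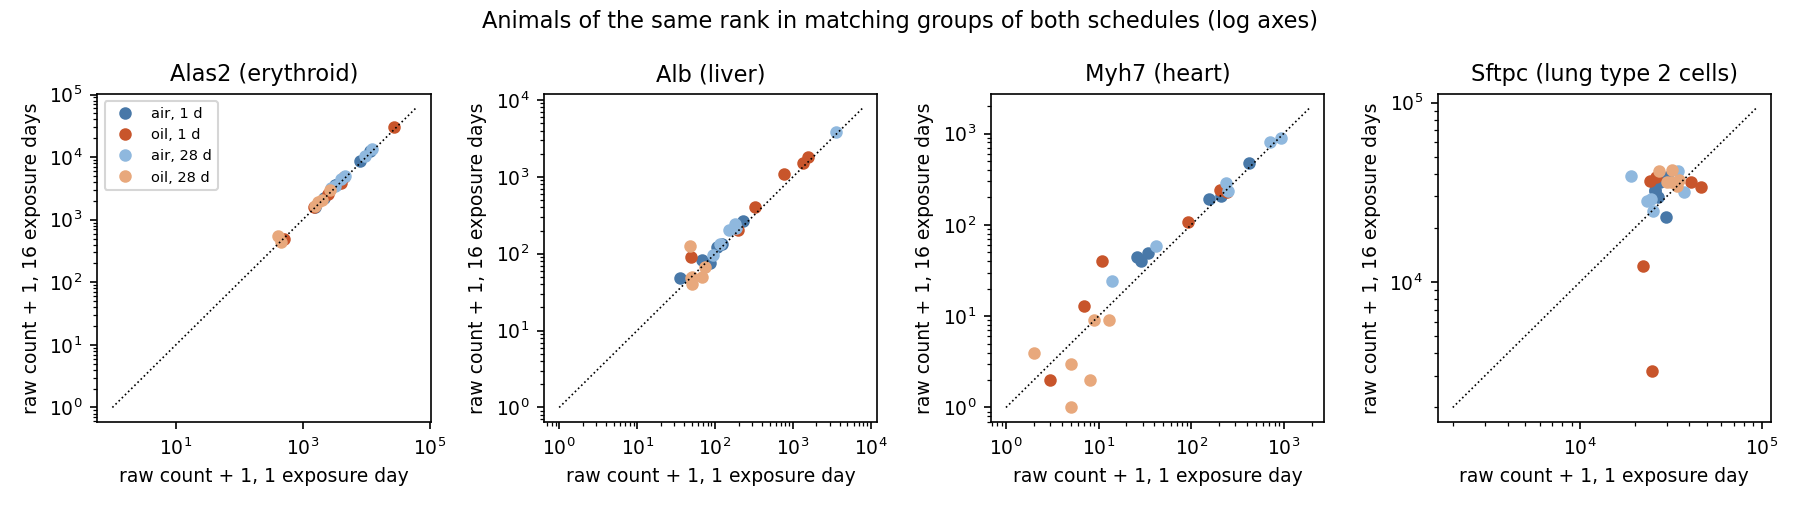
Raw counts plus 1 (log axes) of Alas2, Alb, Myh7 and Sftpc in the 24 pairs of animals of the same rank, single exposure on the x axis and 16 exposure days on the y axis, with the dotted line marking equal counts. Alas2 lay near the line in every pair, up to 27026 and 30019 counts, whereas Sftpc in the pair of animals 5 and 43 was 24969 and 3203 counts.

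The first comparison asked which genes differed 1 day after a single exposure to oil vapor. Airway genes had lower values in oil vapor than in air lungs, although no gene passed the test across all genes. Of 17 genes of ciliated cells, which move mucus along the airways, 16 had lower values, with a median log2 fold change of -0.44, and 6 fell when adjusted over the list alone against 0 over all genes tested. The dynein component Dnai2 had a value of -0.59 (SE 0.20) and the cilium assembly gene Ccdc40 -0.59 (SE 0.21). Among 7 mucus and goblet genes 6 were lower, with a median of -0.91, and 4 fell over the list alone, led by the gel-forming mucin Muc5b at -2.26 (SE 0.57) and Bpifb1 at -2.14 (SE 0.59). Among 11 club cell genes 9 were lower (median -0.37), 1 of them over the list alone, with Scgb3a1 at -2.90 (SE 0.83) and Bpifa1 at -2.26 (SE 0.86).

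Camera with its preset correlation called these 3 lists lower (adjusted p = 1.8e-10, 2.8e-04 and 0.00101). With an estimated correlation the calls were lost, at an adjusted p of 0.424, 0.147 and 0.424. It also called 13 cardiac muscle genes, which rat pulmonary veins express, all lower with a median of -1.12 (adjusted p = 4.7e-04, and adjusted p = 0.669 with an estimated correlation). Myl7 stood at -1.77 (SE 0.70) and Myl4 at -1.27 (SE 0.62). The summed heart transcripts ranged from 84.9 to 1037 CPM in the air and from 108 to 472 CPM in the oil vapor libraries. Lower values with a camera call were also found for glucocorticoid-responsive genes (14 of 15, median -0.30), immediate early genes (16 of 20, -0.28), cholesterol synthesis (16 of 20, -0.15) and xenobiotic phase 1 enzymes (20 of 26, -0.09). Their adjusted p values were 8.3e-04, 8.3e-04, 0.00101 and 0.00237, and 0.668, 0.693, 0.669 and 0.363 with an estimated correlation. Examples were the clock gene Per1 at -0.95 (SE 0.30), Zbtb16 at -1.31 (SE 0.49), Fosb at -1.65 (SE 0.66), Hsd17b7 at -0.41 (SE 0.13) and Ephx2 at -0.48 (SE 0.17).

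Higher values were found for 24 of 28 interferon response genes (median 0.19, camera adjusted p = 8.3e-04), among them Isg15 at 0.45 (SE 0.17). The adjusted p was 0.693 with an estimated correlation. Genes of natural killer and cytotoxic cells were higher in 13 of 14 cases (median 0.24, adjusted p = 0.00912, and adjusted p = 0.693 with an estimated correlation), with Ccl5 at 0.43 (SE 0.17). Ribosomal protein genes, a sign of RNA quality, were higher in 24 of 26 cases (median 0.08, adjusted p = 0.0139, and adjusted p = 0.697 with an estimated correlation). Of 19 complement and acute phase genes, 4 rose and 2 fell over the list alone, and fry's mixed test gave an adjusted p of 1.1e-05. The clotting gene Fgb, which the liver list also holds, had a value of 2.92 (SE 0.87), whereas Lbp had -0.92 (SE 0.19) and the complement inhibitor Serping1 -0.66 (SE 0.17). Summed liver transcripts reached 647, 690.4 and 515 CPM in oil vapor animals 16, 7 and 5, against at most 247 CPM in the air group.

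The 5 genes with the smallest p were all lower and did not pass. They were Rnf208 at -1.22 (SE 0.23), Rph3al at -0.58 (SE 0.11), Enpp3 at -0.62 (SE 0.12), Fam13a at -0.48 (SE 0.10) and Lbp at -0.92 (SE 0.19). Rph3al, linked to vesicle release, averaged 16.9 ± 1.71 CPM (SD, n = 6) in oil vapor and 25.2 ± 3.50 CPM in air. Enpp3, an ectonucleotidase, averaged 35.1 ± 6.38 and 54.2 ± 3.86 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 14820 genes changed (smallest adjusted p = 0.124), while 1494 genes had an unadjusted p below 0.05 against 741 given by chance. DESeq2 called 19 genes and limma-voom 1, and 3 were called without animal 16.

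The second comparison concerned 1 day after 16 exposure days. Mal2, a membrane protein of polarized epithelia, fell by 0.35 on the log2 scale (SE 0.06, adjusted p = 0.0255), from 317 ± 26.7 CPM in air to 250 ± 13.2 CPM in oil vapor (SD, n = 6 each), and all 6 oil vapor animals lay below all 6 air animals. The next genes by p did not pass. The phosphatase gene Ptprt had a value of -0.93 (SE 0.17, adjusted p = 0.0734). Cyp2b1, a major cytochrome P450 of rat lung, averaged 291 ± 28.0 CPM against 381 ± 24.7 CPM in air, and the interferon-induced Bst2 averaged 34.8 ± 10.7 CPM against 21.1 ± 3.01 CPM (adjusted p = 0.0989 for both). Hnrnpa2b1 at 0.44 (SE 0.09) and the caveolin Cav2 at -0.28 (SE 0.06) had the same adjusted p. Mean levels of Mal2 and Cyp2b1 in the oil vapor group lay below those of both 28-day groups, while mean Bst2 in the air group at 1 day lay below the other 3 groups, as the plot of single animals shows.

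**Figure D2:**
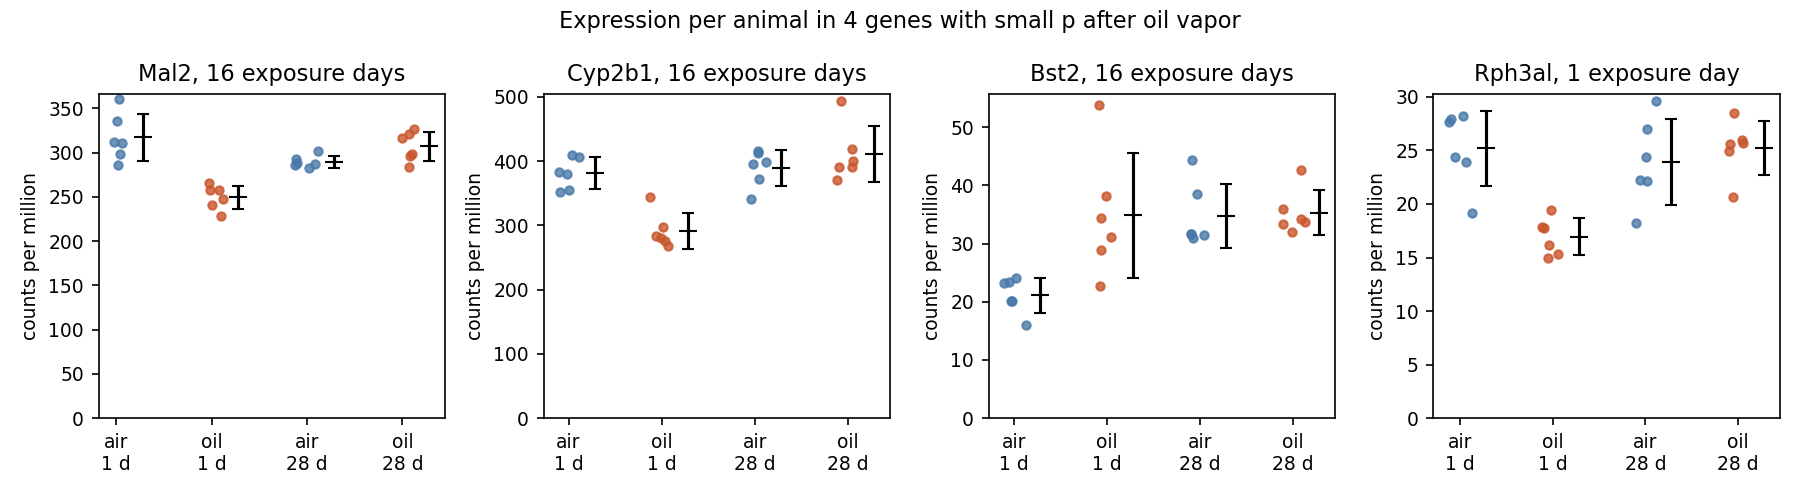
CPM of Mal2, Cyp2b1 and Bst2 after 16 exposure days and of Rph3al after the single exposure, 1 point per animal, with mean and SD beside each group of 6 animals. In Mal2 the oil vapor animals at 1 day lay between 229 and 265 CPM, below the lowest air animal at 286 CPM.

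Xenobiotic enzymes had mostly lower values after 16 exposure days. Of 26 phase 1 enzymes 22 were lower, with a median of -0.11 and 1 fall over the list alone, that of Cyp2b1 at -0.39 (SE 0.07), with Cyp4b1 at -0.37 (SE 0.12). Of 19 phase 2 enzymes 18 were lower (median -0.12), with Sult1a1 at -0.22 (SE 0.10). Camera called both lists (adjusted p = 0.00538 and 0.00106), and lost both with an estimated correlation (adjusted p = 0.547 and 0.398). Alveolar epithelial genes were lower by small amounts. Of 13 type 1 cell genes 11 were lower (median -0.14, adjusted p = 0.00159, and adjusted p = 0.567 with an estimated correlation), as were 13 of 17 type 2 cell genes (median -0.07, adjusted p = 0.0367, and adjusted p = 0.741 with an estimated correlation). Pdpn had a value of -0.20 (SE 0.08) and Sftpc -0.30 (SE 0.13), which was -0.19 without animal 43. Mesothelial genes were lower in 9 of 9 cases (median -0.35, adjusted p = 0.00106, and adjusted p = 0.567 with an estimated correlation), with Upk1b at -0.90 (SE 0.30). Lower lists of lipid metabolism were cholesterol synthesis (18 of 20, median -0.12), fatty acid synthesis (12 of 15, -0.09) and lipid-laden macrophages (13 of 18, -0.09). Their adjusted p values of 0.00126, 0.00367 and 0.0378 became an adjusted p of 0.662, 0.547 and 0.7 with an estimated correlation. Sqle stood at -0.34 (SE 0.17), Acaca, which commits carbon to fatty acid synthesis, at -0.24 (SE 0.07), and the cholesterol exporter Abca1 at -0.30 (SE 0.10).

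Genes of lymphocytes and neutrophils had higher values in the same comparison, whose oil vapor group held animal 43. Without that animal these lists kept their direction, but whether each call held is not reported here. All 14 B and plasma cell genes (median 0.35), all 17 T cell genes (0.35), 13 of 14 natural killer genes (0.29) and 10 of 13 neutrophil genes (0.59) were higher. Camera gave an adjusted p of 8.7e-04, 0.00126, 0.00173 and 0.0114, which became an adjusted p of 0.567, 0.7, 0.662 and 0.7 with an estimated correlation. Tnfrsf13c had a value of 0.62 (SE 0.29), Bcl11b 0.56 (SE 0.26), Ctsw 0.77 (SE 0.30) and the alarmin S100a9 1.20 (SE 0.47). Not all immune lists were higher: 8 of 14 alveolar macrophage genes (median -0.11, camera adjusted p = 0.16) and 6 of 10 genes of MHC class II presentation (median -0.02, adjusted p = 0.742) were lower. So were 9 of 11 genes of eosinophils, mast cells and basophils (median -0.56, adjusted p = 0.0204, and adjusted p = 0.607 with an estimated correlation). Immediate early genes were higher in 18 of 20 cases (median 0.33, adjusted p = 1.5e-05, and adjusted p = 0.567 with an estimated correlation), with Egr1 at 1.00 (SE 0.37). Interferon response genes were higher in 22 of 28 cases (median 0.12, adjusted p = 0.0114, and adjusted p = 0.725 with an estimated correlation), 1 of them, Bst2, over the list alone. Rsad2, at 2.25 (SE 0.90), had a value of -0.88 without animal 43, and its pair correlation across schedules was 0.995. Beside these groups, all 11 erythroid genes were higher (median 2.01, adjusted p = 0.0311, and adjusted p = 0.852 with an estimated correlation), with Hbb at 2.15 (SE 0.64). Erythroid transcripts took 4.76% of the counts of animal 43 and at most 0.531% in the other oil vapor animals of that group. The erythroid list turned the other way without animal 43 (adjusted p = 0.0883) and with a surrogate variable (adjusted p = 0.348). Ribosomal protein genes were higher in 25 of 26 cases (median 0.19, adjusted p = 0.0136, and adjusted p = 0.852 with an estimated correlation), and turned the other way without animal 43 (adjusted p = 1.1e-04), with a surrogate variable (adjusted p = 0.312) and with other-tissue scores (adjusted p = 0.539).

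Of 15005 genes tested after 16 exposure days at 1 day, 1 fell and 0 rose, with 1394 at an unadjusted p below 0.05. Without animal 43, 32 genes were called, 17 higher and 15 lower, among them Mal2, Cyp2b1, Ptprt, Cav2 and Bst2. DESeq2 called 90 genes and limma-voom 93, whereas 0 were called with all 48 libraries, no filter on low counts, only the 12 libraries compared, other-tissue scores or a 1.5-fold minimum, 0 without animals 36, 37, 38, 44, 45 or 48, and 2 without animals 39, 40 or 47.

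The third comparison concerned 28 days after the single exposure. Transcripts of blood and heart had lower values in oil vapor than in air lungs. All 11 erythroid genes were lower (median -1.97), and all 11 fell over the list alone against 0 over all genes, with the Rh-associated Rhag at -2.23 (SE 0.65) and Alas2 at -2.38 (SE 0.74). All 10 platelet genes were lower (median -1.54), 7 over the list alone, with Gp9 at -2.37 (SE 0.58) and Clec1b at -2.20 (SE 0.60). Of 13 cardiac muscle genes 11 were lower (median -1.53), 9 over the list alone. The slow myosin gene Myh7 averaged 1.14 ± 0.712 CPM in oil vapor and 85.9 ± 83.4 CPM in air (SD, n = 6), a value of -6.21 (SE 1.19), and Myl3 stood at -7.33 (SE 1.42). Camera gave an adjusted p of 2.1e-15, 3.1e-14 and 1.2e-10, which became an adjusted p of 0.155, 0.155 and 0.236 with an estimated correlation. In the air group the bone marrow transcripts summed to 685 to 3634 CPM and the heart transcripts to 97.5 to 1739.6 CPM, against 134 to 609.8 and 20.6 to 559.7 CPM in oil vapor. Liver transcripts summed to 1267 CPM in air animal 17, to 240.3 to 296 CPM in the other air animals and to 205 to 255 CPM in oil vapor. Rnr1 and Rnr2 together took 0.573 to 2.85% of the counts in air and 0.364 to 0.784% in oil vapor. These ribosomal RNA symbols were not resolved here as nuclear or mitochondrial. Among air animals the share was highest, 2.85 and 2.54%, in animals 19 and 20, which held the most heart transcripts (1739.6 and 1208 CPM). In oil vapor, animal 32 held the most heart transcripts (559.7 CPM) with a share of 0.409%. The share cannot be read as a sign of RNA quality alone.

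Neutrophil genes were lower in 11 of 12 cases (median -0.50, adjusted p = 5.6e-07, and adjusted p = 0.233 with an estimated correlation), with Fcnb at -0.66 (SE 0.19), 1 fall over the list alone. With scores of other-tissue transcripts as covariates, added after the data were seen, the neutrophil list turned the other way (adjusted p = 0.855). Ribosomal protein genes, a sign of RNA quality, were lower in 19 of 26 cases (median -0.09, adjusted p = 0.0023, and adjusted p = 0.601 with an estimated correlation), and turned the other way with those scores (adjusted p = 0.0026) and with a surrogate variable (adjusted p = 0.0097). Immediate early genes were lower in 20 of 20 cases (median -0.26), respiratory chain genes in 19 of 24 (-0.05), cholesterol synthesis genes in 18 of 20 (-0.15) and fatty acid synthesis genes in 12 of 15 (-0.09). Camera's adjusted p values were 0.00138, 4.7e-04, 4.99e-04 and 0.00168, and with an estimated correlation the adjusted p was 0.601, 0.521, 0.572 and 0.236. Egr1 had a value of -1.01 (SE 0.42), Ndufa9 -0.42 (SE 0.10), Sqle -0.24 (SE 0.12), the desaturase Scd -0.41 (SE 0.12) and its regulator Srebf1 -0.39 (SE 0.12). Antioxidant enzymes (12 of 16 lower, median -0.12) and targets of the oxidative stress factor NRF2 (18 of 22 lower, median -0.06) had adjusted p values of 0.00741 and 0.0253, and an adjusted p of 0.155 and 0.236 with an estimated correlation. Their examples were Gpx1 at -0.90 (SE 0.32), an enzyme also abundant in red cells, and the ferritin gene Fth1 at -0.59 (SE 0.21). Gpx1 turned sign with a surrogate variable (0.0049) and with other-tissue scores (0.048), and its pair correlation across schedules was 0.928. Of 17 circadian clock genes, 4 rose and 1 fell over the list alone, led by Nr1d2 at 0.79 (SE 0.23) and Nr1d1 at 1.68 (SE 0.49), while camera gave an adjusted p of 0.203.

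At 28 days after the single exposure the smallest p belonged to Myh7, Myl3, Ttr at -5.31 (SE 1.13), Serpinb11 at -2.15 (SE 0.46) and the oxygen carrier myoglobin, Mb, at -4.55 (SE 0.97). Their pair correlations across schedules were 0.924, 0.921, 0.828, 0.813 and 0.647 in that order. None of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.154). That test called 0 of 14820 genes, with 1217 at an unadjusted p below 0.05. DESeq2 called 24 genes, limma-voom 0, and a fit of only the 12 libraries compared 16. Without animal 5, a 1-day animal of the same fit left out after the data were seen, 69 genes were called, 67 of them lower, and 9 were called without animal 17.

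The fourth comparison, 28 days after 16 exposure days, showed the same blood and heart groups lower. It cannot be taken as an independent repeat, since counts of these genes went with the rank of the animal across schedules. The correlation over same-rank pairs was 0.997 for Alas2, 0.984 for Clec1b, 0.924 for Myh7 and 0.899 for Myl2. All 13 cardiac muscle genes were lower, with a median of -2.79, and 11 fell over the list alone against 0 over all genes. Myh7 averaged 0.633 ± 0.582 CPM in oil vapor and 84.2 ± 86.6 CPM in air (SD, n = 6), a value of -6.93 (SE 1.42), with Myl2 at -7.37 (SE 1.58). Camera gave an adjusted p of 5.5e-25, and an adjusted p of 0.057 with an estimated correlation. All 11 erythroid genes (median -1.72) and all 10 platelet genes (median -1.43) were lower, with Alas2 at -2.10 (SE 0.98) and Clec1b at -2.08 (SE 0.88). Camera's adjusted p values of 9.5e-08 and 2.1e-07 became an adjusted p of 0.42 for both with an estimated correlation. The air animals held 180 to 1759 CPM of heart transcripts, against 28.96 to 268 CPM in oil vapor. Rnr1 and Rnr2 together took 0.513 to 3.03% of their counts, against 0.408 to 1.45% in oil vapor. Fatty acid oxidation genes were lower in 17 of 24 cases (median -0.10, adjusted p = 0.00637, and adjusted p = 0.44 with an estimated correlation), and 2 fell over the list alone. These were Fabp3 at -3.48 (SE 0.86) and Cpt1b at -1.11 (SE 0.31), both forms used by heart muscle. With other-tissue scores, the erythroid, platelet and fatty acid oxidation lists turned the other way (adjusted p = 0.0197, 0.856 and 0.0634), with Fabp3 at 0.056 and Cpt1b at 0.15. Those scores hold Alas2 and heart transcripts that themselves differed between these groups, so the reversals are no independent check.

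Genes of natural killer cells, T cells and neutrophils, higher at 1 day after 16 exposure days, had lower values at 28 days. All 14 natural killer genes were lower (median -0.41), as were 15 of 17 T cell genes (-0.16), all 13 neutrophil genes (-0.17) and 22 of 28 interferon response genes (-0.08). Camera's adjusted p values were 4.7e-09, 0.00743, 0.0116 and 0.00943, and with an estimated correlation the adjusted p was 0.42, 0.766, 0.766 and 0.766. Eomes, a master regulator of cytotoxic lymphocytes, had a value of -0.67 (SE 0.22), Gzmm -0.66 (SE 0.24) and Cd3g -0.64 (SE 0.24). B and plasma cell genes were lower in 9 of 14 cases (median -0.06, camera adjusted p = 0.707). With other-tissue scores as covariates, added after the data were seen, the T cell list turned the other way (adjusted p = 0.011), as did the neutrophil list (adjusted p = 0.221), with S100a9 at 0.17 and S100a8 at 0.33. Respiratory chain genes were lower in 22 of 24 cases (median -0.14, adjusted p = 1.3e-08, and adjusted p = 0.42 with an estimated correlation), with Ndufv2 at -0.19 (SE 0.07). Cell cycle genes were lower in 21 of 27 cases (median -0.15, adjusted p = 0.0285, and adjusted p = 0.766 with an estimated correlation). The member with the smallest p went the other way, the cell division regulator Foxm1 at 0.41 (SE 0.14). Ribosomal protein genes were lower in 25 of 26 cases (median -0.14, adjusted p = 9.05e-04, and adjusted p = 0.77 with an estimated correlation). Respiratory chain, cell cycle and ribosomal protein genes turned the other way with other-tissue scores (adjusted p = 0.0571, 0.0179 and 7.7e-11).

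Higher values at 28 days after 16 exposure days were found for all 20 immediate early genes (median 0.30), 23 of 26 extracellular matrix genes (0.09), all 7 mucus genes (0.46) and 16 of 17 type 2 cell genes (0.08). Camera's adjusted p values were 2.3e-06, 0.00399, 0.00943 and 0.0284, and with an estimated correlation the adjusted p was 0.42, 0.766, 0.472 and 0.766. Fos had a value of 0.90 (SE 0.34), the growth factor Tgfb1 0.28 (SE 0.14), Muc5b 1.25 (SE 0.64) and the lung identity factor Nkx2-1 0.30 (SE 0.13). Matrix and type 2 cell genes turned the other way with other-tissue scores (adjusted p = 0.0596 and 0.738). The 5 genes with the smallest p were Myh7, Myl2, Mb at -5.78 (SE 1.25), Eef1a2 at -3.22 (SE 0.70) and Myl3 at -8.22 (SE 1.84), all with an adjusted p of 0.415. EdgeR's test called 0 of 15005 genes, with 729 at an unadjusted p below 0.05 against 750 given by chance. DESeq2 called 21 genes, limma-voom 0, and a fit of only the 12 libraries compared 137, of which 135 were lower, whereas 61 genes, all lower, were called without animal 43, which was left out here after the data were seen.

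Across the 4 oil vapor contrasts, camera with its preset correlation called 15, 17, 14 and 16 of 45 lists, in the order given above. None of these calls held with an estimated correlation, and fry called 0 lists by direction in each. Fry's mixed test called 1 list at 1 day and 4 at 28 days after the single exposure, the latter complement and acute phase, hypoxia and glycolysis, fatty acid oxidation and respiratory chain genes (adjusted p = 0.0134, 0.0134, 0.0353 and 0.0353), and 0 after 16 exposure days. The plot of list medians sets 20 lists side by side. NRF2 targets had medians of 0.08 and 0.02 at 1 day after the single and repeated exposures, and 0.00 at 28 days after the repeated exposure (camera adjusted p = 0.481, 0.739 and 0.415). Targets of the aryl hydrocarbon receptor, which induces Cyp1 enzymes, were called in none of the 4 contrasts (camera adjusted p = 0.256, 0.0894, 0.987 and 0.311). Neither were cytokine and acute inflammation genes (camera adjusted p = 0.469, 0.716, 0.214 and 0.389).

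**Figure D3:**
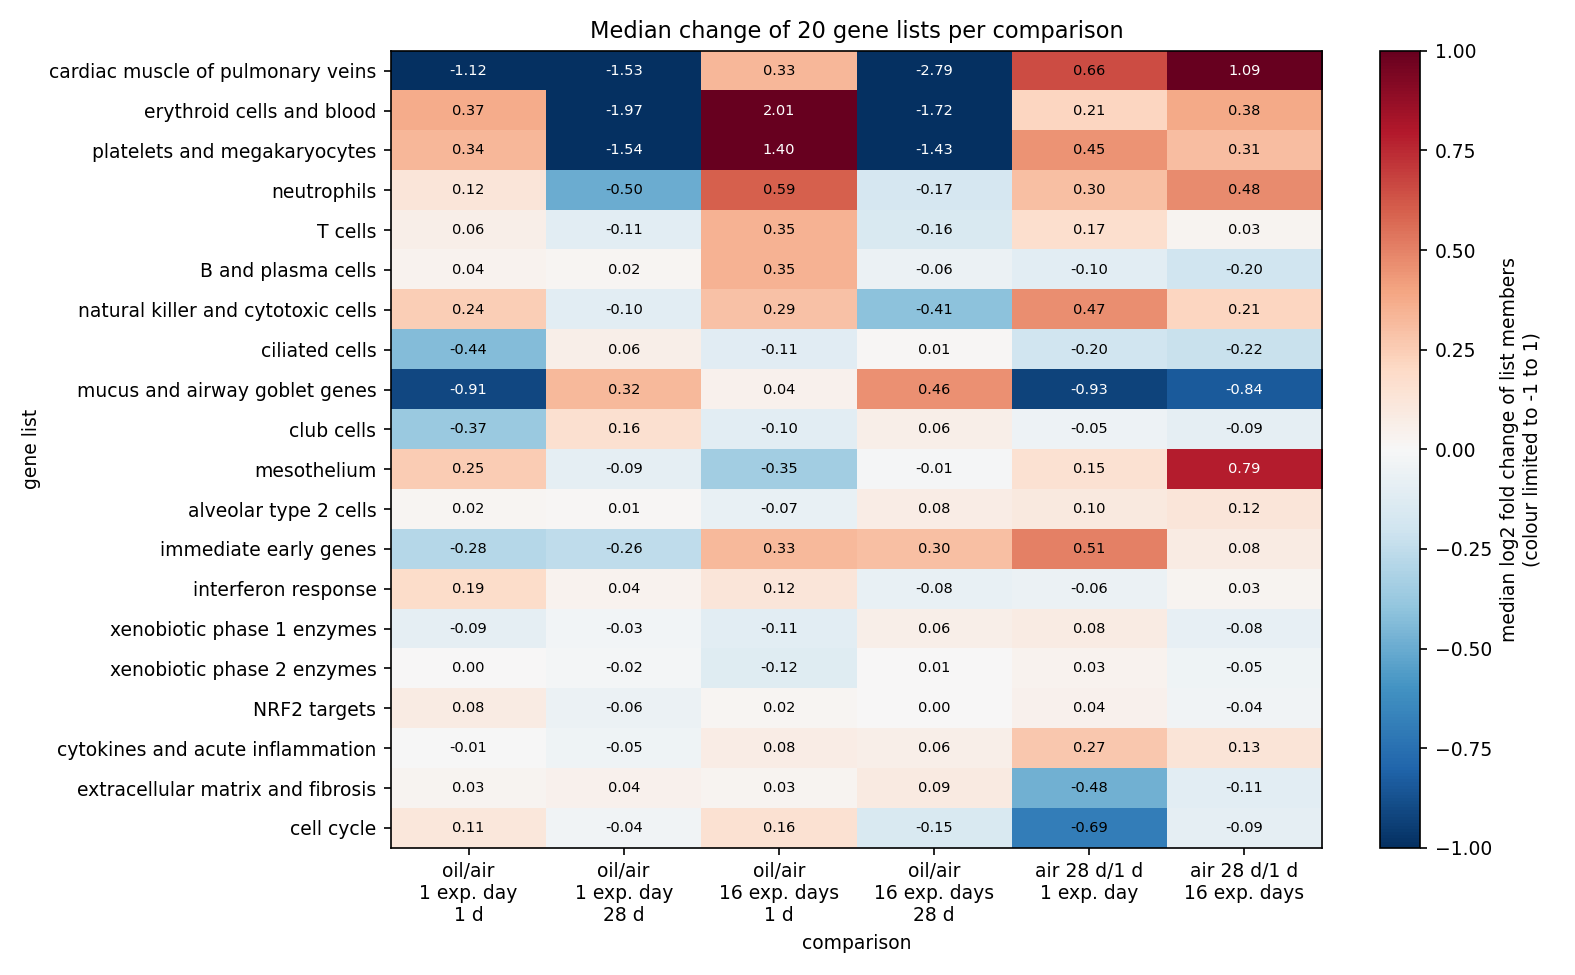
Median log2 fold change of the measured members of 20 gene lists (y axis) in the 4 oil vapor contrasts and the 2 contrasts of air groups (x axis), with the value written in each cell and colour limited to the range from -1 to 1. Cardiac muscle genes had oil vapor medians of -1.12 at 1 day and -1.53 at 28 days after the single exposure. After the repeated exposure these medians were 0.33 and -2.79. Extracellular matrix genes had a median of -0.48 in the air groups of the single exposure.

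Whether an oil vapor effect differed between 1 and 28 days was tested directly. After 16 exposure days the difference was past the threshold for Ptprt, a receptor tyrosine phosphatase. Its oil vapor value was -0.93 (SE 0.17) at 1 day and 0.49 (SE 0.17) at 28 days, a difference of 1.42 (SE 0.24, adjusted p = 0.0472, n = 6 per group). The call was lost with RLE size factors, with no filter on low counts, and with other-tissue scores, with or without animal 43 (adjusted p = 0.0517, 0.0674, 0.503 and 0.797, over a range of 0.0016 to 0.797 among all settings). The next genes did not pass: Mal2 differed by 0.43 (SE 0.08, adjusted p = 0.0691), Alb by -7.18 (SE 1.32), Cdhr2 by 1.89 (SE 0.36) and Bhmt by -6.73 (SE 1.39). EdgeR called 1 of 15005 genes, with 1171 at an unadjusted p below 0.05. After the single exposure it called 0 of 14820 genes, with 1160 at an unadjusted p below 0.05, while DESeq2 called 21 genes and limma-voom 0. The smallest p there belonged to the liver transcripts Ttr at -8.06 (SE 1.41), Alb at -6.20 (SE 1.13), Pzp at -6.49 (SE 1.19), Apob at -6.07 (SE 1.17) and Cps1 at -5.99 (SE 1.17), with an adjusted p of 0.0572 to 0.0688. Alb had oil vapor values of 2.58 (SE 0.77) at 1 day and -3.62 (SE 0.83) at 28 days, where animal 17 held 3592 counts and the other air animals at most 183, and it was among the transcripts whose counts went with the rank of the animal.

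Whether the effect at 1 day differed between 16 exposure days and 1 was tested over all 48 libraries. Of 15322 genes, 6 had a higher and 1 a lower effect after 16 exposure days. Zdhhc17, a palmitoyltransferase, had effects of -0.19 (SE 0.05) and 0.21 (SE 0.05), a difference of -0.40 (SE 0.08, adjusted p = 0.0279). Lbp, which binds bacterial lipopolysaccharide, had effects of 0.51 (SE 0.22) and -0.92 (SE 0.21), a difference of 1.43 (SE 0.30, adjusted p = 0.0393). Differences were also past the threshold for the claudin-domain gene Cldnd1 at 0.89 (SE 0.17), the myosin light chain Myl12b at 1.29 (SE 0.27), Rab27a, a GTPase of vesicle secretion, at 1.08 (SE 0.22), Wbp2 at 1.01 (SE 0.21) and LOC306766 at 0.64 (SE 0.12). Without animals 5 and 43, left out after the data were seen, 4 genes were called, and Zdhhc17, Cldnd1 and LOC306766 were among them, whereas 25 were called without animal 43 alone. With a block of the same-rank pairs, also added after the data were seen, 6 genes were called, 4 of them shared, and Myl12b, Lbp and LOC306766 no longer passed. At 28 days edgeR called 0 of 15322 genes (smallest adjusted p = 0.546), with 796 at an unadjusted p below 0.05. DESeq2 called 0 genes there and limma-voom 2. The genes with the smallest p were Fbxo21 at 0.56 (SE 0.13), Atxn7l2 at 0.76 (SE 0.19), Kcna3 at 0.86 (SE 0.21), Scn3b at 0.88 (SE 0.22) and Scamp3 at 1.09 (SE 0.27).

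Air groups at 28 days and 1 day were compared as background, since the animals differed in age and day without oil vapor. After the single schedule, genes of the extracellular matrix and of cell division fell. Of 26 matrix genes 18 fell and 0 rose (19 adjusted over the list alone), with a median of -0.48. The fibrillar collagen Col3a1 fell from 4643 ± 510.4 to 2252 ± 364 CPM (SD, n = 6), Col1a1 from 503 ± 126 to 173 ± 38.2 CPM, and elastin, Eln, by 1.29 on the log2 scale (SE 0.14). The metalloprotease Adamts17 fell from a mean of 100 ± 12.1 to 48.7 ± 5.65 CPM (log2 fold change -1.04, SE 0.10, adjusted p = 1.2e-06), and the microfibril gene Fbn1 by 0.71 on the log2 scale (SE 0.07). Of 27 cell cycle genes 14 fell and 0 rose (24 over the list alone), with a median of -0.69, among them Mki67 at -0.83 (SE 0.11) and Cenpf at -1.05 (SE 0.15). Both lists stayed past the threshold with an estimated correlation (adjusted p = 2.8e-04 and 0.00213) and with fry (adjusted p = 1.2e-06 and 1.1e-05). In the oil vapor groups Col3a1 and Adamts17 lay at like levels, whereas Col1a1 at 1 day averaged 328 ± 58.8 CPM in oil vapor, with every oil vapor animal below every air animal (log2 value -0.61, a fall over the list alone that did not pass over all genes), as the plot of matrix genes shows.

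**Figure D4:**
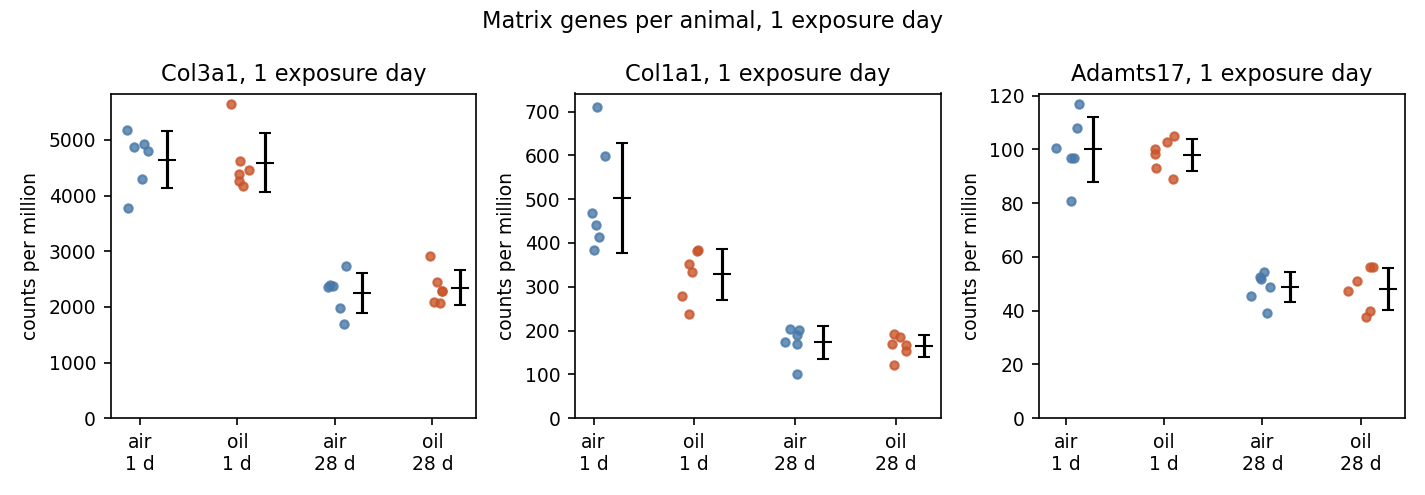
CPM of Col3a1, Col1a1 and Adamts17 in the 4 groups of the single exposure, 1 point per animal, with mean and SD beside each group of 6 animals. Col3a1 averaged 4643 and 4593 CPM in air and oil vapor at 1 day, and 2252 and 2347 CPM at 28 days, while Col1a1 averaged 503 and 328 CPM at 1 day, and 173 and 164 CPM at 28 days.

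Immediate early genes were higher at 28 days in all 20 cases (median 0.51), and 5 rose (12 over the list alone), among them Klf2 at 0.77 (SE 0.17) and Dusp1 at 0.87 (SE 0.20). Camera called them (adjusted p = 2.1e-11), and the adjusted p was 0.283 with an estimated correlation. Of 14 natural killer genes 2 rose (5 over the list alone), Gzma at 0.81 (SE 0.19) and Ccl5 at 0.65 (SE 0.16), with a camera adjusted p of 1.1e-07, and an adjusted p of 0.283 with an estimated correlation. Of 19 cytokine genes 2 rose (4 over the list alone), Il1a at 0.87 (SE 0.14) and Tnfaip3 at 0.53 (SE 0.10), with a camera adjusted p of 6.05e-04, and an adjusted p of 0.126 with an estimated correlation. Of 20 cholesterol synthesis genes 3 fell (5 over the list alone), among them Hmgcs1 at -0.60 (SE 0.12) and Hsd17b7 at -0.57 (SE 0.14). Camera gave an adjusted p of 9.8e-06, and an adjusted p of 0.388 with an estimated correlation. Among 26 phase 1 enzymes 3 rose and 1 fell, with Cyp4b1 at 0.45 (SE 0.06) and the aryl hydrocarbon target Cyp1a1 at -2.19 (SE 0.35). In all, 149 of 14820 genes rose and 332 fell.

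After the repeated schedule, fewer genes differed between the air groups, 40 higher and 9 lower at 28 days among 15005, with 215 called without animal 43. Dynll2, a dynein light chain, rose from 48.7 ± 5.08 to 84.1 ± 13.2 CPM (log2 fold change 0.79, SE 0.10, adjusted p = 4.8e-04), and the sterol-binding Osbp fell from 139 ± 7.15 to 114 ± 4.04 CPM. Hnrnpa2b1 rose by 0.57 (SE 0.09), Nolc1 by 0.34 (SE 0.06) and the proteasome ATPase Psmc3 by 0.59 (SE 0.10). Aryl hydrocarbon receptor targets were lower in 6 of 7 cases, with a median of -0.46. Cyp1b1, at -0.78 (SE 0.17, adjusted p = 0.0396), fell over all genes and 3 fell over the list alone, and Ugt1a6 stood at -0.46 (SE 0.13). That list stayed past the threshold with an estimated correlation (adjusted p = 0.0174) and with fry (adjusted p = 0.00151). All 9 mesothelial genes were higher (median 0.79), 8 over the list alone and 0 over all genes, with Upk3b at 1.09 (SE 0.29), and camera's adjusted p of 1.1e-07 became an adjusted p of 0.276 with an estimated correlation. Unfolded protein response genes were higher in 16 of 18 cases (median 0.13, adjusted p = 6.9e-04, and adjusted p = 0.469 with an estimated correlation), and the chaperone Hsp90b1 rose by 0.40 (SE 0.08). Cardiac muscle genes were higher in 11 of 13 cases (median 1.09, adjusted p = 0.0289, and adjusted p = 0.65 with an estimated correlation).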

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

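The fits of the highest other split, the joint relabelling of pairs, and tests of reads shared across schedules and of blood or other tissue in each animal's own lung piece were chosen after the result was seen, while those of a duplicate library, a common lung change and chance were written before it.

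Among 58 groups tested for a sample far from the rest, 7 held one, against 2.9 given by chance. Summed liver transcripts stood at 1267 CPM in animal 17 (others of its group 240.3 to 296 CPM) and at 1511 CPM in animal 82 (227 to 330.2 CPM). Heart transcripts stood at 472 CPM in animal 5 (108 to 239 CPM). Spleen and bone marrow transcripts stood at 6003 CPM in animal 5 (165 to 716 CPM), 3634 CPM in animal 23 (685 to 1666 CPM) and 20470 CPM in animal 43 (191 to 883 CPM). Col1a1 in animal 20 lay far below its group, at 100.2 CPM against 169 to 204 CPM.

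Oil vapor effects that differed between groups in an edgeR interaction test were those of Ptprt between 28 days and 1 day after 16 exposure days, by 1.42, and of 7 genes between 16 exposure days and 1, each measured 1 day after the last. The latter were Zdhhc17 at -0.40, LOC306766 at 0.64, Cldnd1 at 0.89, Myl12b at 1.29, Rab27a at 1.08, Wbp2 at 1.01 and Lbp at 1.43.

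Blood transcripts, liver transcripts in the oil vapor groups at 1 day (r = 0.936) and the air groups at 28 days (r = 0.981), and heart transcripts in the latter (r = 0.974), stood at like raw counts in animals of the same rank in both schedules, as did the summed brain list (r = 0.92), with 1 of 8 genes over 0.8. Blood or other tissue within each animal's own lung piece is argued against by the correlation of 0.988 between unrelated animals for marrow transcripts, a sum mostly of Alas2. Erythroid transcripts gave 0.942, with 10 of 11 genes over 0.8. A library present under both schedules is argued against by the smallest chi-square per gene within a pair, 2.69. Other-tissue reads shared by libraries of the same rank stay open: the log2 ratio of raw marrow counts had an SD of 0.193 over the 24 pairs, against 0.420 after scaling to library size. Over those pairs 174 of 15614 genes had a pair r over 0.8, against at most 5 in any of 100 reorderings within groups. Both results are what such sharing would give, a prediction written after the pattern was seen. The sources used here name no plate, lane or index, so how such reads could be shared was not tested. Summed heart transcripts gave r = 0.223 over all pairs, and 3 of 11 heart genes were over 0.8. Genes with the smallest p at 28 days had higher values, 0.924 for Myh7, 0.921 for Myl3 and 0.899 for Myl2, and 0.647 for Mb.

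Genes, 67 of 69 and 61 of 61 of them lower after oil vapor at 28 days, were called after the single and repeated exposures once animal 5 or animal 43 was left out, with 20 in common, of which 15 had a pair correlation over 0.8. Other-tissue reads shared by libraries of the same rank stay open for part of these calls: 45 of the 69 and 23 of the 61 had such a correlation, as 174 of 15614 genes did. A change in the lung common to both schedules also stays open, with r = 0.413 between the fold changes of both schedules across the 14585 other genes, though these are still paired to a degree (median pair r over all genes 0.303). When oil vapor and air were relabelled alike in both schedules, which keeps the pairs, r of the mean log2 CPM differences had a median of 0.111 and a highest value of 0.434, and 4 of 462 splits, the real one included, reached the real 0.366. That r of fold changes was 0.265 over 965 genes with a negative pair correlation and 0.158 over all genes after adjustment for tissue scores, and both readings are hypotheses found and tested on the same data.

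Chance was examined with 100 splits of the same animals, the real one included. Where the real count was 0, all 100 splits reach it by construction, so the splits say nothing about chance. This held for oil vapor after the single exposure (highest other 1 at 1 day and 3 at 28 days), for oil vapor 28 days after 16 exposure days (highest other 1), for the difference between times after the single exposure (highest other 3) and for the difference between schedules at 28 days (highest other 2). Chance could not be excluded for the real 1 gene 1 day after 16 exposure days, which 6 splits reached (highest other 1), for the real 1 gene that differed between times after 16 exposure days, which 6 reached (highest other 4), or for the real 7 genes that differed between schedules at 1 day, which 5 reached. The highest other split there called 222 genes, several times the real 7, which points to a structure of the samples. That split called 0 genes with other-tissue scores as covariates, 2 without animals 5 and 43 and 127 without animal 43 alone. It put animal 5 in air and animal 43 in oil vapor, whereas both breathed oil vapor in the real grouping. Splits between schedules relabelled each schedule separately and so broke the same-rank pairs. Their count therefore cannot decide about chance for the 7 genes. Chance was excluded for the air groups, where 1 of 100 splits, the real one, reached 481 genes after the single schedule (highest other 4) and 49 after the repeated one (highest other 1).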

How the results depend on the processing

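Settings that left out animals 5 or 43 beyond their own contrast, or that used other-tissue scores or the pair block, were chosen after the data were seen, and all others were planned. Within a schedule, no paired analysis was run, since each animal number occurs in a single group. A block of the 24 same-rank pairs, added after the data were seen, gave 6 calls for the schedule difference at 1 day (4 of the 7 shared) and 0 at 28 days. Of the single genes and lists named, 3114 values kept direction and side of the threshold over all settings, 107 came past it, 217 fell short of it, 183 of the latter being lists, and 37 changed direction. Of the values that kept both, 2944 were of genes, many of which had not passed in the main test, and 170 of lists. Among those that changed direction, 18 were of genes and 19 of lists. Depth limits low genes most, since a count of 3 was up to 1.95 CPM. For every result that moved or reversed below, the cause was not tested.

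Counts of genes called moved as follows. For oil vapor after the single exposure at 1 day (main 0), 1 with a surrogate variable, 19 with DESeq2, 1 with limma-voom, and 0 to 3 leaving out animals in turn (1 without animal 1, 3 without 16). At 28 days (main 0), 24 with DESeq2, 16 with only the 12 libraries, 1 with scores, 10 without animal 5 with scores, and 0 to 69 leaving out animals (9 without 17, 69 without 5). After 16 exposure days at 1 day (main 1), 20 with a surrogate variable, 90 with DESeq2, 93 with limma-voom, 7 without animal 43 with scores, and 0 with a 1.5-fold minimum, all 48 libraries, no filter, only the 12 libraries or scores. Leaving out animals gave 0 to 32 there (0 without 36, 37, 38, 44, 45 or 48, 2 without 39, 40 or 47, 32 without 43). At 28 days (main 0), 21 with DESeq2, 137 with only the 12 libraries, 4 with scores, and 0 to 61 leaving out animals (61 without 43). For the difference between times after the single exposure (main 0), 21 with DESeq2, 11 with no filter and 7 without animal 5 with scores. After 16 exposure days (main 1), 5 with a surrogate variable, 36 with all 48 libraries, 47 with DESeq2, 3 with limma-voom, 3 without animal 43, and 0 with no filter, scores, RLE size factors, or scores without animal 43. For the difference between schedules at 1 day (main 7), 25 with a surrogate variable, 61 with DESeq2, 34 with limma-voom, 23 with scores, 4 without animals 5 and 43, and 5 to 25 without 5 or 43. At 28 days (main 0), 2 with limma-voom. For the air groups, 170 with a 1.5-fold minimum after the single schedule (main 481). After the repeated one (main 49), 208 with a surrogate variable, 13 with a 1.5-fold minimum, 131 with all 48 libraries, 191 with DESeq2, 244 with limma-voom, 123 with only the 12 libraries, and 215 without animal 43.

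Genes whose value changed sign were these. Rsad2 1 day after 16 exposure days had -0.52 with a surrogate variable, -0.73 with limma-voom, -0.021 with scores, -0.073 without animal 43 with scores, and -0.88 to 2.58 leaving out animals. At 28 days after the single exposure, Mmp8 had 0.0067 without animal 5 with scores, Gpx1 0.0049 with a surrogate variable and 0.048 with scores, and Ube2c 0.12 with scores. At 28 days after 16 exposure days with scores, Uqcrc1 had 0.0040, Fabp3 0.056, Cpt1b 0.15, Cd247 0.24, Fcgbp -0.12 (-0.14 without animal 43 as well), S100a9 0.17, S100a8 0.33 and Ccnb1 0.016.

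Lists whose camera direction reversed, with the adjusted p of the reversed direction, were mesothelial genes at 1 day (0.955) and neutrophil genes at 28 days (0.855) after the single exposure, both with scores. Ribosomal protein genes reversed at 28 days after the single exposure with scores (0.0026) and with a surrogate variable (0.0097). At 1 day after 16 exposure days they reversed with a surrogate variable (0.312), with scores (0.539) and without animal 43 (1.1e-04), and erythroid genes with a surrogate variable (0.348) and without animal 43 (0.0883). At 28 days after 16 exposure days, scores reversed type 2 cell (0.738), cell cycle (0.0179), erythroid (0.0197), matrix (0.0596), neutrophil (0.221), respiratory chain (0.0571), platelet (0.856), fatty acid oxidation (0.0634), ribosomal protein (7.7e-11) and T cell genes (0.011). Blood and heart transcripts summed in the scores differed between these groups, so the scores take up part of the change tested.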

Other observations

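Tests of list scores in the air groups were chosen after the air results were seen.

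The fall of matrix and cell cycle genes between the air groups was larger after the single schedule. Mean log2 CPM of 26 matrix genes changed by -0.53 after the single and by -0.12 after the repeated schedule, a difference of 0.41 (two-sided permutation p = 0.0187, adjusted p = 0.0249 over 4 lists). Cell cycle genes changed by -0.65 and -0.09, a difference of 0.55 (permutation p = 0.00908, adjusted p = 0.0246). Phase 1 enzymes had values of 0.06 and -0.19, a difference of -0.25 (permutation p = 0.0123, adjusted p = 0.0246), and immediate early genes 0.51 and 0.09 (permutation p = 0.245). Mean matrix levels at 1 and 28 days were 7.91 and 7.38 log2 CPM after the single and 7.36 and 7.25 after the repeated schedule. Cell cycle levels were 3.58 and 2.94, and 3.01 and 2.92, so the single group at 1 day stood apart in both. The permutations shuffled both times within each schedule, so p refers to no change in either, rather than to equal changes. Matrix and cell cycle genes had already been called lower after the single schedule. Their p values here therefore cannot decide whether the changes of the schedules were unequal. The animals of the schedules differed in age and day, so no cause was assigned.

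Further lists called by camera with its preset correlation went in opposite directions in different contrasts. At 1 day, mesothelial genes were higher in 9 of 9 cases after the single exposure (median 0.25, adjusted p = 0.016, and adjusted p = 0.695 with an estimated correlation) and lower in 9 of 9 after 16 exposure days. With other-tissue scores, added after the data were seen, the list turned the other way at 1 day after the single exposure (adjusted p = 0.955). Heat shock genes were lower in 15 of 16 cases at 1 day after the single exposure (median -0.16, adjusted p = 0.00894, and adjusted p = 0.693 with an estimated correlation) and higher in 14 of 16 at 28 days (median 0.12, adjusted p = 0.0253, and adjusted p = 0.627 with an estimated correlation).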
